A study of Homo sapiens with 2 samples.

How the data were processed

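The series profiled lysine pyruvylation, an acyl mark on lysine residues, in HEK293T cells, an established human embryonic kidney cell line that was labelled wild type. Per the labels' protocols, permeabilised cells on concanavalin A beads were incubated with an antibody, here taken to be that against pyruvyl-lysine (pan-Kpy), and a transposase tethered through a secondary antibody cut and tagged nearby DNA (CUT&Tag). Libraries were sequenced as paired-end reads on an Illumina instrument. The 2 samples form 1 group, Kpy, with replicates 1 and 2. The labels do not say whether the replicates were separate cultures, so p-values refer to these libraries and their peaks. The protocol text, which both samples share, names an antibody against pyruvyl-lysine or one against lactyl-lysine without saying which sample had which. Both samples were taken as pyruvyl-lysine libraries from their Kpy titles and the series design text, and the peak tables cannot check this. No control library was used here.

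Per the submitters' processing notes, the authors used Bowtie and SAMtools with the hg38 build. Their versions, the peak caller's settings and any control track are not given in the sources used here. Each library has its own deposited peak table, so the peaks used here were called per sample, and whether the authors also pooled replicates is not given in the sources used here. Per the file headers, each table lists for every peak the position, the fold enrichment, which is a ratio of the pileup to the local background of that library, and the pileup, a signal of fragment coverage whose scaling is not given. Per the file headers, the authors also deposited the −log10 p-value and the −log10 q-value of each peak, with the nearest transcript, its gene, an annotation class and the distance from the transcription start site (TSS). The column names are those that MACS and ChIPseeker write. The lowest deposited −log10 q-value was 2.02 in both tables, as a q-value threshold of 0.01 would leave. The deposited length was 1 bp more than the width in every row, so starts may lie 1 bp off, and positions are given as deposited. Peak numbers skipped 5 values in replicate 1 and 4 in replicate 2, and the sources used here do not say why. All scores of single peaks below are the authors' values, and they were used to describe, rank and filter peaks within a list.

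Peaks on chromosomes 1 to 22 and X entered the comparisons, which left 896 of 900 peaks in replicate 1 and 1385 of 1389 in replicate 2. The remaining 4 in each list are mitochondrial. Total reads per library are unknown, because the tables hold peaks alone. The local background was recomputed from each peak as (pileup + 1) / fold enrichment − 1, which assumes that the caller added 1 to both terms. Its lowest value serves as a relative measure of depth. Intervals cover counting error only: Wilson intervals for shares, exact binomial intervals for gene lists and exact Poisson intervals for counts per chromosome, all at 95%.

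Peaks were called shared when they overlapped by at least 1 bp. The overlap was set against 1000 random placements of the peaks within their own chromosome (bedtools 2.31.1, one-sided permutation p, smallest possible value 0.000999). Scores of shared and unshared peaks were compared by a two-sided permutation test of the difference of medians with 100000 resamples, and agreement of shared peaks by Spearman's rho with a permutation p. Gene positions and biotypes came from a RefSeq table of GRCh38.p14, whose gene identifiers match those in the deposited tables. That table has no strand and no genome sequence was used here. The placement of peaks by feature was therefore tested as within 1 kb of either end of a protein-coding gene, inside a gene body, or outside genes, and exons were not separated from introns. Chromosome spans ran to the last annotated gene, with assembly gaps left in. Benjamini-Hochberg adjustment ran over 3 features and 2 replicates.

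A protein-coding gene counted as having a promoter peak when the authors assigned it a peak within 1 kb of its TSS. It also counted when its 5′ end, or either end where the tables did not show its strand, lay within 1 kb of a peak that the authors placed within 1 kb of a TSS. Of the 422 genes that counted in both replicates, 91 had no known strand. The 26 gene lists, fixed before the data were examined, were tested by a two-sided Fisher's exact test against all other protein-coding genes, 19970 in all, with Benjamini-Hochberg adjustment over the lists. On simulated data with the same 19970 genes, lists made 10-fold more frequent were called in 100% of 100 runs for DNA replication and cell cycle (45 genes), 100% for oxidative phosphorylation (67) and 84% for fatty acid synthesis and oxidation (28). With no list changed, 2% of the runs had any call. Smaller gains, lists of fewer than 28 genes and lists made less frequent were not simulated, so these rates do not extend to them. Genes were drawn independently, unlike genes that share a peak.

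Genes were named by a rule fixed before the data were examined. It takes the 12 protein-coding genes with the highest promoter peak in both replicates, by the mean of the within-replicate ranks of fold enrichment. It adds the 3 highest members of each list with a promoter peak in both replicates, the 3 highest unshared peaks of each replicate, and HAT1, EP300 and SIRT3, which the series title names. Other genes were chosen after their values were seen. Values of some genes that the rule or a count takes in are not reported here.

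Alternatives covered the overlap rule, the placement of random peaks, the score column, the promoter width, a stricter peak threshold, the annotation, the gene assignment and each replicate on its own. The base composition of peaks, lists matched on CpG content and placements for base composition were planned and not run, since they need a genome sequence. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.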

Results

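Lysine pyruvylation was mapped in HEK293T cells with 2 CUT&Tag libraries of 1 group, here called replicates 1 and 2, whose antibody is taken from the sample titles. The authors' tables listed 896 nuclear peaks for replicate 1 and 1385 for replicate 2, a ratio of 1.55. Median peak width was 373.5 bp (quartiles 317 and 501.5) and 405 bp (quartiles 330 and 545). The peaks covered 400.4 kb and 659.7 kb of the genome. Most peaks were low. The median fold enrichment over local background was 5.01 (range 3.59 to 19.08) in replicate 1 and 4.79 (range 3.22 to 18.5) in replicate 2, and the median pileup was 9.41 and 10.6. The lowest local background was 0.442 and 0.545, which puts replicate 2 at 1.23 times the depth of replicate 1 if the background tracks depth.

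The first comparison asked which pyruvyl-lysine peaks both replicates held. The strongest shared promoter peak overlapped the TSS of KBTBD3, near an end of AASDHPPT, the latter encoding a phosphopantetheinyl transferase, on chromosome 11 (106077044 to 106077448 in replicate 1, hg38), with a fold enrichment of 9.86 in replicate 1 and 9.46 in replicate 2. It was followed by the promoter of ZBTB37 on chromosome 1 (7.88 and 8.37) and that of ATF7, a CREB-family transcription factor, on chromosome 12 (7.79 and 8.17). The ATF7 peak also covers the start of the readthrough gene ATF7-NPFF. In all, 391 peaks were shared, which is 43.6% (Wilson interval 40.4 to 46.9%) of replicate 1 and 28.2% (25.9 to 30.7%) of replicate 2.

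Random placement within chromosomes gave a mean of 0.441 and 0.495 shared peaks and at most 3 and 4 (one-sided permutation p = 0.000999 in each, the smallest that 1000 placements can give). Placement that kept promoter peaks at gene ends gave means of 16.8 and 16.7. It drew on both ends of all protein-coding genes alike, so it likely understates the overlap that peaks confined to TSSs would have. Shared peaks were higher than unshared ones. Their median fold enrichment was 5.23 against 4.89 in replicate 1 and 4.98 against 4.74 in replicate 2 (two-sided permutation p = 1e-05 in each, the smallest that the resamples can give). In the highest 10% by fold enrichment, 72.2% of replicate 1 peaks and 46.0% of replicate 2 peaks were shared, against 38.9% and 23.7% in the lowest 10%. The contrast was steeper by the other scores. By pileup the shares were 85.6% and 56.8%, against 11.1% and 7.91%. By −log10 q-value they were 80% and 56.1%, against 17.8% and 7.91%. Across the 391 shared peaks, which are not independent replicates, fold enrichment correlated between replicates with a Spearman's rho of 0.44 (bootstrap interval 0.35 to 0.52, permutation p = 0.0001, the smallest possible).

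**Figure D1:**
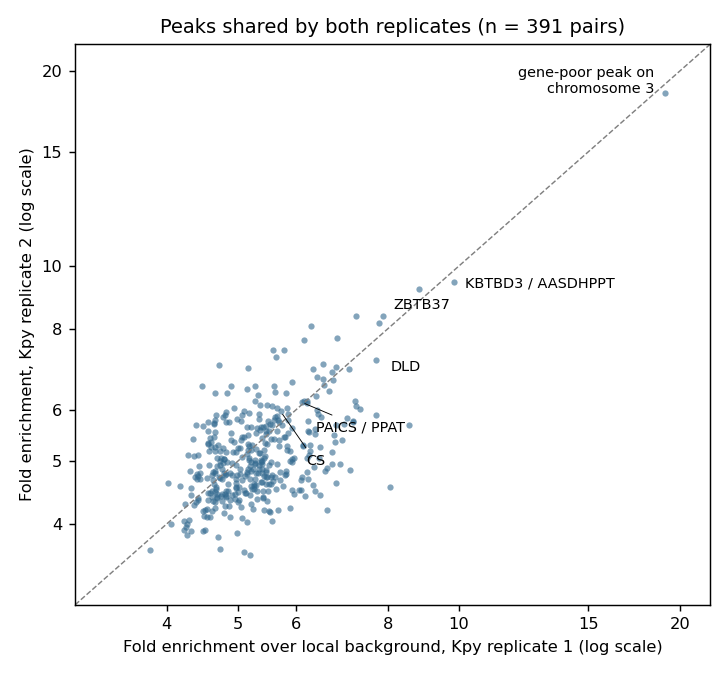
Fold enrichment over local background of the 391 peaks shared by both Kpy replicates, replicate 1 on the x axis and replicate 2 on the y axis, both without unit on log scales. Each point is a pair of overlapping peaks and the dashed line marks equal values; the KBTBD3 and AASDHPPT peak lies at 9.86 and 9.46, and Spearman's rho over all pairs is 0.44.

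**Figure D2:**
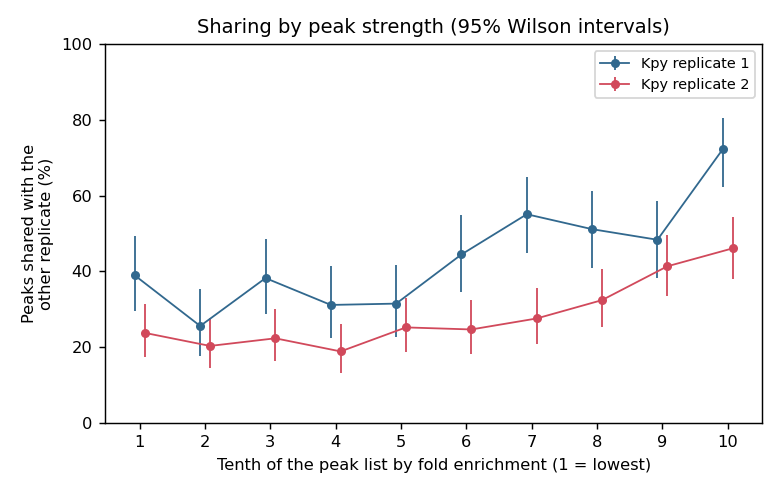
Percent of peaks shared with the other replicate (y axis) by groups of 10% of the peak list, ordered by fold enrichment (x axis), for Kpy replicates 1 and 2. Bars are Wilson intervals; the highest group reaches 72.2% in replicate 1 and 46.0% in replicate 2.

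The second comparison asked where in the genome the peaks lay. They lay mostly at promoters. By the authors' annotation, 737 of 896 peaks of replicate 1 (82.3%, Wilson interval 79.6 to 84.6%) and 1159 of 1385 of replicate 2 (83.7%, 81.6 to 85.5%) were within 1 kb of a TSS. Distal intergenic peaks made up 8.48% and 6.64%, intronic peaks 5.92% and 6.71%, and exonic peaks 1.67% and 1.81%. Among the promoter peaks, 73.8% and 78.5% overlapped the TSS itself. The peak centre lay a median of 48 bp (bootstrap interval 24 to 71) and 42 bp (27 to 62) downstream of it. Centres spread to both sides, with quartiles of −121 and 146 bp in replicate 1 and −126 and 154 bp in replicate 2. Only 57.7% and 56.9% lay downstream.

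Against random placement, 68.8% of replicate 1 peaks lay within 1 kb of an end of a protein-coding gene, where 2.87% would by chance (ratio 23.9). In replicate 2 it was 69.7% against 2.76% (ratio 25.2). Peaks inside gene bodies were fewer than by chance, at ratios of 0.427 and 0.446, and so were peaks outside genes, at 0.243 and 0.211. Each of these 6 differences had an adjusted one-sided permutation p of 0.000999, the smallest possible. Every peak counted in a single class, gene ends first, so the excess at gene ends left fewer peaks for the other classes. Their lower shares are therefore not separate results and do not show that peaks away from gene ends avoid gene bodies.

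The third comparison asked which genes carried a promoter peak. In replicate 1, 874 of 19970 protein-coding genes did, in replicate 2 1366, and 422 (2.11%) did in both. Independent lists of these sizes would share 59.8 genes, so the overlap was 7.06 times that (Fisher's exact test, two-sided, p = 1.40e-270). A single peak can count for several genes, so genes are not independent units and this p-value is likely too small. The expected number also takes every gene as equally likely to carry a peak. By the authors' assignment alone, 308 genes were in both. Among the 12 highest were 2 zinc finger and BTB-domain genes, ZBTB37 and ZBTB3 (7.24 and 8.38 in replicates 1 and 2). DLD, which encodes the dihydrolipoamide dehydrogenase subunit of the pyruvate dehydrogenase complex, had peaks of 7.72 and 7.16 at its TSS on chromosome 7 (107891119 to 107891580 in replicate 1). Several top peaks lay within 1 kb of ends of adjoining or overlapping genes, as those at RAB2B and TOX4 (6.81 and 7.75) and at SWT1 and TRMT1L (7.08 and 6.94). NCOA5, encoding a nuclear receptor coactivator, had 6.80 and 6.97.

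Because the series title ties pyruvylation to glycolytic flux, lists of metabolic genes were examined first. No glycolysis gene of 22 had a promoter peak in both replicates (exact p = 1.00), and 3 had one in a single replicate, among them ENO1 (4.99, replicate 1) and PFKM (6.28, replicate 2). Of 23 genes of pyruvate transport and the pyruvate dehydrogenase complex, DLD had one in both, and DLAT, PDP1 and PDHX had one in replicate 2, PDHX through a peak assigned to APIP. Of 20 TCA cycle genes, CS, encoding citrate synthase, had one in both (5.71 and 5.97). MDH1, IDH1 and OGDH (6.55) had one in replicate 2, and SUCLG1 had one in replicate 1. With a peak required in both replicates, neither list differed detectably from other genes (adjusted exact p = 0.830 each). Only 0.486 and 0.423 members were expected. Counting a peak in either replicate, 4 of 23 and 5 of 20 did, which did not pass adjustment (exact p = 0.315 and 0.131). Genes with a promoter peak in a single replicate, here and in the lists that follow, were chosen after their values were seen. AASDHPPT, ATF7-NPFF, TOX4, TRMT1L, ENO1, PDHX, IDH1, PPAT and HNRNPA1 counted only through peaks assigned to a neighbouring or overlapping gene, with their strand unknown, and are uncertain.

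The fatty acid list had 3 of 28 members in both replicates, 5.10 times the share of other genes, with an exact p of 0.0208 that did not pass adjustment (0.270). Among them were ACADM (5.46 and 4.81) and ACACA (5.01 and 4.69). The ACACA peaks of the replicates lay at different promoters, that of replicate 2 being assigned to TADA2A. In nucleotide and serine synthesis, PAICS and PPAT, which encode purine synthesis enzymes, counted through 1 peak at the TSS of PAICS on chromosome 4 (6.10 and 6.16), and 2 of 23 members counted (adjusted exact p = 0.548). In the hypoxia list, 2 of 22 counted, EGLN1 (5.21 and 4.83) and DDIT4 (4.24 and 3.95), with the same adjusted p.

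Among lists of constitutive processes, RPS19 (5.65 and 5.56) was the 1 cytosolic ribosomal protein gene of 78 with a promoter peak in both replicates. HNRNPK (6.20 and 6.19) and HNRNPA1 (4.59 and 5.34, at a peak assigned to CBX5) were the 2 of 39 splicing factor genes. NDUFA11 (5.004 and 4.32) was the 1 of 67 oxidative phosphorylation genes, and HSPA8 (4.89 and 5.52) the 1 of 24 chaperone genes. CDK2 counted among 45 DNA replication and cell cycle genes only through a peak assigned to RAB5B (4.41 and 4.39), with its strand unknown, and is uncertain. Of 509 ZNF genes, 7 counted, led by ZNF131 (6.41 and 6.73), ZNF333 (6.14 and 7.69) and ZNF33B (6.48 and 5.85). None of these lists differed from other genes after adjustment.

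Olfactory receptor genes, which are mostly silent outside sensory neurons, had no promoter peak in both replicates among 390 members. For this list 8.24 would be expected and the exact binomial interval reaches 0.941% (exact p = 0.000482, adjusted 0.0125). It was the 1 of 26 lists past the threshold, and 2 of 26 had an unadjusted exact p under 0.05. In all, 14 of the 26 lists had no member with a promoter peak in both replicates. The olfactory receptor call was lost against lists matched on chromosome and gene length (adjusted permutation p = 0.276). It was also lost under the authors' gene assignment (adjusted exact p = 0.138) and in the upper part of the lists by fold enrichment (adjusted exact p = 0.463). None of these settings can add a gene, so the count had to stay at 0 and does not speak for the call. Matched lists expected 5.09 members. Counting a peak in either replicate, 1818 genes (9.10%) had one. Heat shock and chaperone genes were then more frequent, at 7 of 24 (3.21 times other genes, adjusted exact p = 0.0383), and olfactory receptors (0 of 390, 1.78e-15) and keratin-associated proteins (0 of 94, 0.00276) less frequent. Matching on chromosome and gene length was run for peaks in both replicates only, where it lowered the expected number of keratin-associated protein genes from 1.99 to 0.220, so their call here is not shown to hold apart from these properties. Besides HSPA8, the chaperone genes were HSPH1, HSP90AA1 and TCP1 in replicate 2, and HSPD1, HSPE1 and CCT3 in replicate 1. HSPD1 and HSPE1 counted through 1 peak. TCP1, CCT3 and HSPE1 counted only through peaks assigned to neighbouring genes, with their strand unknown, and are uncertain. Neither replicate alone called the list (adjusted exact p = 0.125 and 0.226).

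**Figure D3:**
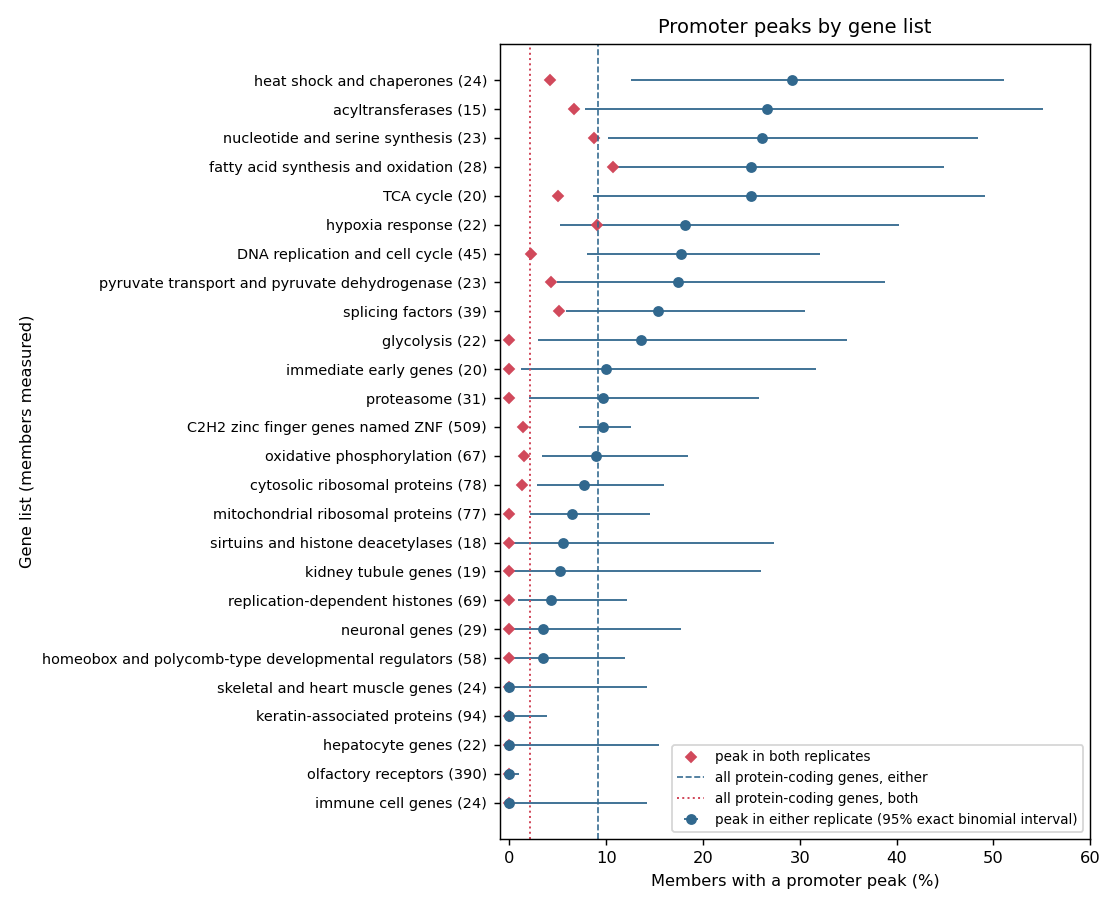
Percent of members with a promoter peak (x axis) for each of the 26 gene lists (y axis, members measured in parentheses). Circles are members with a peak in either replicate with exact binomial intervals, diamonds are members with a peak in both, and vertical lines are all protein-coding genes at 9.10% and 2.11%; olfactory receptors and keratin-associated proteins are at 0.

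Of the enzymes that the series title names, none had a promoter peak by the rule. The peak nearest to HAT1, a histone acetyltransferase gene on chromosome 2, was 2188762 bp away in replicate 1 and 487731 bp in replicate 2. For SIRT3, a mitochondrial deacylase gene on chromosome 11, the distances were 269721 and 339188 bp. EP300, encoding the acetyltransferase p300 on chromosome 22, had a replicate 2 peak 1046 bp from its start (41091233 to 41091546, fold enrichment 5.61), which the authors assigned to MIR1281. Its nearest replicate 1 peak was 201402 bp away. Other acyltransferase genes with promoter peaks were KAT6B in both replicates (4.58 and 4.10), NAA50 and KAT2B in replicate 2, and KAT8 in replicate 1, so 1 of 15 counted in both (adjusted exact p = 0.830). Of 18 sirtuin and histone deacetylase genes, SIRT5 had a peak in replicate 2 alone.

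Peaks of a single replicate were compared with shared ones. The highest unshared peaks of replicate 1 were at the promoters of GSTZ1 (7.46), GET3 (6.97) and MYPOP (6.91), and those of replicate 2 at NT5C3A (7.61), TRIM13 (7.36) and FGD5-AS1 (7.10). Promoter peaks made up 87.2% of shared peaks, against 78.4% of unshared peaks in replicate 1 (Fisher's exact test, two-sided, p = 0.000584) and 82.3% in replicate 2 (p = 0.0290). The latter difference was 3.51 points and did not pass the exact test (p = 0.159) when a shared peak had to overlap by 50% of each. No gene list differed between genes with peaks in both replicates and genes with a peak in 1 (lowest adjusted exact p = 1).

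Peak density differed between chromosomes. The genome carried 0.296 peaks per Mb in replicate 1 and 0.457 in replicate 2. Chromosomes 1 (0.599 and 0.856), 6 (0.416 and 0.656) and 19 (1.02 and 1.40) had Poisson intervals above that mean in both replicates, and 7 chromosomes lay below it in each. Per 100 protein-coding genes, chromosome 1 had 7.23 (6.12 to 8.49) and 10.3 (8.99 to 11.8), and chromosome 17 had 1.97 (1.25 to 2.95) and 3.42 (2.44 to 4.66), against 4.49 and 6.94 for the genome. Chromosome 19 was then at 4.14 (3.16 to 5.32) and 5.65 (4.49 to 7.01), with the mean inside both intervals. Peaks per 100 genes correlated between the replicates over 23 chromosomes (Pearson's r = 0.93, Spearman's rho = 0.84, permutation p = 1e-05 for each, the smallest possible, adjusted over 5 relations 5e-05). Without the 2 chromosomes farthest from the median, r was 0.90.

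**Figure D4:**
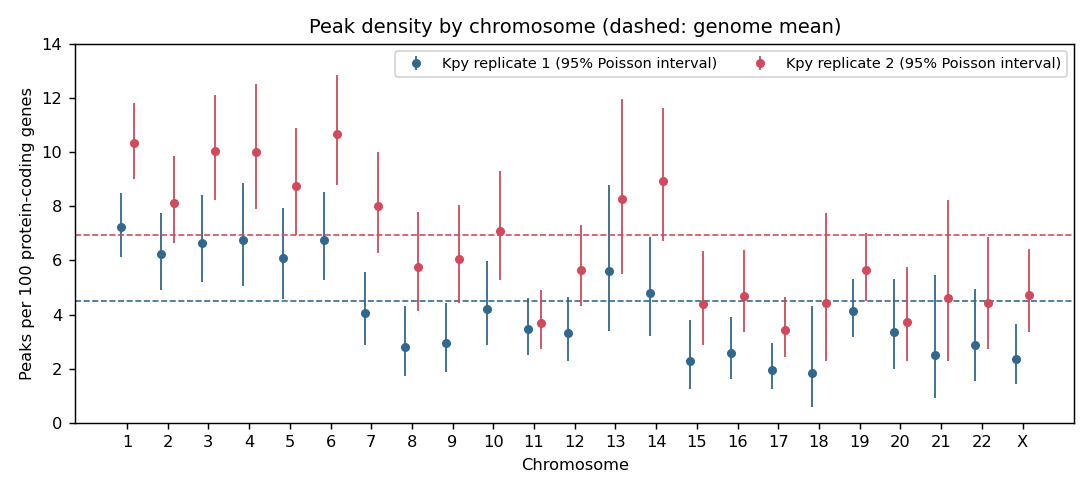
Peaks per 100 protein-coding genes (y axis) on each chromosome (x axis) in Kpy replicates 1 and 2. Bars are Poisson intervals and dashed lines the genome means of 4.49 and 6.94; chromosome 1 lies above its mean and chromosome 17 below it in both replicates.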

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

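All tests in this part were chosen after the results were seen. The mitochondrial peaks lie outside the comparisons above and carried by far the highest pileups. The highest reached 2768.5 in replicate 1 and 2274.9 in replicate 2. Both replicates had 4 such peaks, with fold enrichments of 3.94 to 5.26 and 3.96 to 5.27 over a median local background of 568 and 474, against 1.05 and 1.35 at nuclear peaks.

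Fewer than 50% of the peaks of either list were shared. Greater depth of replicate 2 as the whole cause would leave most replicate 1 peaks inside the replicate 2 list, and only 43.6% were. Calls near the detection threshold may account for part of it. The share found in the other replicate was higher in the top than in the bottom 10% by fold enrichment. The smaller difference, in replicate 2, was 22.3 points. The threshold appears to lie on the q-value, and by −log10 q-value the contrast was steeper. The shares were then 80% against 17.8% in replicate 1 and 56.1% against 7.91% in replicate 2. That pattern holds for any source of weak peaks. Even the top 10% of replicate 2 had only 46.0% shared by fold enrichment and 56.1% by −log10 q-value. The design has 1 group, so no biological explanation was tested.

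Most peaks sat at promoters. Regional gene density alone does not account for it, because peaks moved by 20 to 200 kb came near gene ends far less often. The ratio of observed to moved was 14.6 or more. The smaller ratio under placement within chromosomes was 23.9, so regional gene density may account for a part. Cutting of open chromatin without the antibody cannot be told apart from pyruvyl-lysine signal, since no control library was used here. Genes of ribosomal proteins, mitochondrial ribosomal proteins, proteasome, splicing and oxidative phosphorylation, whose promoters are open in dividing cells, had a promoter peak in either replicate at 8.90% (26 of 292), against 9.11% of other genes. The odds ratio of 0.976 (exact interval 0.624 to 1.47) leaves both explanations open. Its value depends on which lists were pooled. Chaperone genes (7 of 24, 29.2%) and DNA replication and cell cycle genes (8 of 45, 17.8%) were left out. No biological explanation was tested.

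Peaks were unevenly spread along the genome. Counting all nuclear peaks, chromosomes with more peaks per gene had a higher local background at their peaks (Spearman's rho 0.60, permutation p = 0.003, in replicate 1 and 0.67, p = 0.0008, in replicate 2, Benjamini-Hochberg adjusted 0.00435 and 0.0019). Pearson's r was 0.56 and 0.65, and 0.44 and 0.59 without the 2 farthest chromosomes. Local read density, as extra copies of a chromosome in this aneuploid line would give, may contribute. Copy number was not measured. The background was recomputed at called peaks alone, so these values cannot tell read density from enrichment. Gene density may too: of 5 equal groups of genes by local gene density, the sparsest had a promoter peak more often than the densest, 6.51% against 3.28% in replicate 1 (ratio 1.98) and 10.5% against 5.13% in replicate 2, while over whole chromosomes the relation of peaks per gene with gene density had the same direction and did not pass adjustment (rho −0.13 and −0.42, permutation p = 0.554 and 0.0486, adjusted p = 0.554 and 0.0607). Gene density stood in for base composition, which was not measured, and no biological explanation was tested.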

How the results depend on the processing

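Lists matched on chromosome and gene length, either end of every gene, peaks moved by 20 to 200 kb and the density comparison without olfactory receptor and keratin-associated protein genes were chosen after the data were seen. Of 430 alternative values, 374 kept their direction and their side of the threshold or stayed within the spread. Many of these belong to gene lists that were not called, and lists at 0 must stay at 0 under stricter rules. The count therefore says little about robustness. The excess of shared peaks over chance kept its direction and passed its test under all 5 alternatives (33.7 to 44.1 points in replicate 1, 21.8 to 28.6 in replicate 2). So did the ratio at gene ends under its 5 (9.72 to 44.2) and the agreement of shared peaks under its 2 other score columns (rho 0.35 and 0.59). The number of lists past the threshold, 1, was 1 to 2 with 1 replicate left out, 3 with a peak in either replicate, and 0 in the upper part by fold enrichment, under the authors' gene assignment and with matched lists. The smaller promoter excess of shared peaks in replicate 2 fell to 3.51 points under reciprocal overlap. Per gene, 6 chromosomes of replicate 1 had an interval above the mean instead of 3. Of the chromosomes whose interval per Mb excluded the mean, chromosome 13 turned above it (1.25 and 1.19 times) and chromosome 19 below (0.922 and 0.815), with the mean inside their intervals per gene. Among the rest, chromosome 4 went from 0.925 and 0.886 to 1.51 and 1.44 times the mean and chromosome 17 of replicate 2 from 1.05 to 0.493, with intervals per gene that excluded it. Chromosomes 11 and 14 of replicate 1 and 2, 5 and 10 of replicate 2 changed side with the mean inside both intervals. The gene lists that reversed were lists not called with a peak required in both replicates, although chaperones were called with a peak in either. As fold over other genes with 1 replicate left out, they ranged from 0.00 to 1.46 for immediate early genes, 0.804 to 1.09 for ZNF genes, 0.664 to 2.08 for glycolysis, 0.993 to 2.55 for pyruvate metabolism and 0.872 to 1.02 for oxidative phosphorylation. With a peak in either replicate, glycolysis was at 1.499, proteasome at 1.06, immediate early genes at 1.099 and ZNF genes at 1.06. DNA replication was at 0 within 500 bp, 0.993 within 3 kb, 0.965 in gene bodies, and 0 in the upper part and under the authors' assignment. Oxidative phosphorylation was at 2.01 within 3 kb and 1.16 against matched lists, proteasome at 1.40 in gene bodies and 1.74 with either end, acyltransferases at 0 in the upper part and with either end, ribosomal proteins at 1.44 in the upper part and 1.13 against matched lists, chaperones at 0 and ZNF genes at 1.57 in the upper part. The cause of these changes was not tested. Base composition of peaks, lists matched on CpG content and placements for base composition were not run. No paired analysis was possible because the series has 1 group. With 422 genes in both lists, a list of 20 to 30 genes expects under 1 member, which limits what its count can show; total reads are unknown, so the part of depth in this was not tested.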

Other observations

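All tests in this part were chosen after the results were seen. Genes of specialised tissues were largely without promoter peaks. Among 118 neuronal, kidney tubule, hepatocyte, muscle and immune cell genes, 2 had one in either replicate, SYT1 and SCNN1A (1.69%, against 9.15% of other genes, two-sided Fisher's exact test p = 0.00193 for the 5 lists pooled). The lists were pooled after their counts were seen. None of the 5 was called alone with a peak in either replicate (lowest adjusted exact p = 0.315). Of 87 families defined by the root of their symbols with at least 20 members, 2 passed Benjamini-Hochberg adjustment in either replicate. The keratin-associated proteins had no peak (adjusted exact p = 0.0185, not matched on chromosome or gene length). The genes whose symbols start with CDC, many but not all of them cell division regulators, had 10 of 33 (30.3%, adjusted exact p = 0.0217). The fixed DNA replication and cell cycle list, with 8 of 45 in either replicate, was not called (adjusted exact p = 0.201). All 10 had a peak in replicate 2: CDC20, CDC25A, CDC25C, CDC27 (6.43), CDC73, CDC14A, CDC5L, CDC40, CDC42EP3 and CDC42BPA. CDC42BPA alone had one in replicate 1 as well, so the family rests on 1 library. Promoter peaks assigned to long non-coding RNA genes numbered 49 (6.65%) in replicate 1 and 85 (7.33%) in replicate 2.

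Among the 391 shared peaks, 17 lay more than 50 kb from a TSS. The highest peak of both lists was one of them, at 93470359 to 93470792 on chromosome 3, with identical borders in both replicates, fold enrichments of 19.08 and 18.5 and pileups of 330.7 and 295. It lies 415621 bp from the nearest TSS, that of PROS1, close to the centromere. A peak on chromosome 16 (46390582 to 46390862, 8.81 and 9.20) lies 87577 bp from a TSS. The immunoglobulin heavy chain constant region on chromosome 14, which spans 105586937 to 105856217 and is expressed in B cells, held 7 peaks in replicate 1 and 6 in replicate 2, counting 20 kb on each side, and 4 in each were shared. The widest nuclear peak of replicate 2 (2555 bp) lay there, 1028 bp from IGHA1, where replicate 1 had a peak of 1010 bp. Whether these regions collect reads from repeated sequence was not tested.

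Several of the highest peaks lay within 1 kb of ends of adjoining genes, as at KBTBD3 and AASDHPPT, and it was asked whether higher peaks do so more often. They did not detectably: in replicate 1, 15.99% of the higher and 19.0% of the lower promoter peaks, split at the median, had facing ends of 2 protein-coding genes within 1 kb (Fisher's exact test, two-sided, p = 0.288), and in replicate 2 18.3% and 17.1% (p = 0.644). Over all promoter peaks it was 17.5% and 17.7%, against 14.7% of all gene ends, a difference that was not tested. The values are not directly comparable. The 1 kb was counted from the borders of a peak but from a single position at gene ends, and both ends of each gene entered.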
